A study of Mus musculus with 6 samples.

How the data were processed

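Small RNA libraries of 6 mouse brain samples were analysed from their deposited tables. Per the labels' protocols, total RNA was extracted with TRIzol, and a library was made from 1 µg of it with the NEBNext small RNA kit and sized to 135 to 155 bp, which holds inserts of 15 to 35 nt. This kit ligates adapters to both ends, and the ligation favours some end sequences, so that counts compare the same miRNA between libraries better than different miRNAs within a library. Per the submitters' processing notes, the tools cutadapt and Bowtie were used; their versions, the genome build and the miRNA reference are not given in the sources used here. The deposited values are whole-number read counts per mature miRNA entry, without normalization, as the values themselves show: totals over all 727 rows differ between libraries, from 2114319 to 2903601. How the 727 rows were chosen is not given in the sources used here.

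The deposited count tables repeat a mature miRNA once for each of its hairpins. Of 50 names with repeated rows, 22 held identical counts in all 6 libraries and 41 agreed within 5% in each, so the rows were read as the same reads listed again, and the row with the highest total was kept. This left 622 names and 1423905 to 2023475 counts per library. Of the tested names, 18 shared their counts with another name, within 5% or 1 count in every library, and could not be told apart. All columns of counts were used. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of at least 51.3 for any pair of libraries of a group, so none was treated as deposited a second time. At these depths 3 counts, taken as the limit that a count of 0 allows, correspond to 1.45 to 2.05 CPM; this limit covers counting error only, since PCR copies are not independent molecules.

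Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test without robust estimation, after filterByExpr with its defaults (minimum count 10, minimum total 15), which left 440 miRNAs, and TMM scaling. The model held the group alone, on all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM values are counts over TMM-scaled library sizes, and standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. The biological coefficient of variation was 25.3%, and the median log2 fold change of all tested miRNAs was −0.054. Exact two-sided permutation tests compared log2 CPM of 3 against 3 libraries, where no p can be below 0.1. miRNAs share hairpins and families and are not independent of one another.

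Before the data were examined, 24 lists of miRNAs were fixed from textbook knowledge of brain cell types, blood, vessels, neighbouring tissues and miRNA families, and 21 had the 3 tested members needed for a list test. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry; adjustment was over the 21 lists. The miR-193 and miR-365, hypoxia-induced and Hox-locus lists had too few members. Calls are also counted adjusted over the list alone. The rule for the miRNAs named in the text was fixed at the same time. It takes the measured members of the miR-193 and miR-365 list, and the miRNAs past the threshold with a group mean of at least 10 CPM and no overlap of the groups, up to 10 in each direction. It also takes the 10 most abundant and up to 4 tested members of each list with the smallest p. Of the 97 miRNAs this rule takes, the text names a part, and miR-141-5p, miR-375-3p and miR-133b-3p were added after their values were seen.

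On counts simulated for this comparison from the means and dispersion of the 440 tested miRNAs, the test recovered 50 of 68 changed by 2-fold (73.5%), 66 of 66 changed by 4-fold and 66 of 66 changed by 8-fold, with 4 false calls among 240 left unchanged. The simulation changed far more miRNAs than passed in the data, with 186 calls against 10. This eases the Benjamini-Hochberg adjustment, so the shares recovered may be too high for the real comparison. The list test recovered 5 of 5 changed lists with 0 of 20 false. Members of the simulated lists varied independently of one another. The estimated correlation was 0.46 in the real epithelial and pituitary list and 0.18 in the Dlk1-Dio3 list, so the false rate does not carry over to these. Alternatives fixed before the data were examined were RLE, upper-quartile and total-count scaling, the 5 most abundant miRNAs left out, no filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust estimation, an unadjusted p with a 2-fold change, and each library left out in turn. Added after seeing the data were the sum of repeated rows, all rows as separate entries, and a fit without the miR-183 and miR-200 groups. Positions of hairpins are from GENCODE vM21 on GRCm38, matched by gene name; the build used for the deposited counts is not given, and no coordinate was taken from the deposited tables. Plots were drawn with matplotlib 3.10.9. The comparison of the 2 groups' deviations uses 1 correlation of their means, because medians over pairs of their members, tried first, count the same movement many times. The scaling comparison uses a list fixed beforehand, because the miRNAs past the threshold, tried first, were chosen by their change. The muscle comparison uses 3 miRNAs. At first miR-133a-3p alone was tried, and the others were added after their higher values were seen. The labels give no batch, so none could be compared.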

Results

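Small RNAs were sequenced from brain tissue of C57BL/6J mice, an inbred laboratory strain, to compare miRNA content after a sham operation with that after global cerebral ischemia-reperfusion. In the second group both carotid arteries were tied for 20 minutes before blood flow was restored. The length of the reperfusion and the part of the brain are not given in the sources used here. Each group held 3 libraries, numbered 3, 6 and 7 for sham and 1, 2 and 3 for ischemia-reperfusion. The labels do not say in so many words that each library came from a separate animal, so the p-values measure the spread between these samples. Total counts, with 1 entry per mature miRNA, were 1644332, 1423905 and 1750612 in sham libraries 3, 6 and 7. They were 1559288, 1627670 and 2023475 in ischemia-reperfusion libraries 1, 2 and 3. Of 622 mature miRNA names, 599 to 612 were detected per library, and the 10 most abundant took 57.3% to 65.9% of a library's counts. Log2 CPM of pairs of sham libraries correlated across miRNAs, which are not independent replicates, with Pearson's r of 0.988 to 0.991, against 0.964 to 0.984 for pairs of ischemia-reperfusion libraries.

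The miRNAs of the miR-183 cluster and of the miR-200 family rose together after ischemia-reperfusion. The miR-183 cluster (miR-183, miR-96 and miR-182) is highly expressed in sensory organs such as the retina and inner ear, and the miR-200 family is abundant in epithelia and represses the transcription factors Zeb1 and Zeb2. miR-183-5p rose 9.75-fold, from 847 ± 349 CPM in sham to 8256 ± 5897 CPM (SD, n = 3 each). miR-182-5p rose 6.64-fold, from 1702 ± 829 to 11295 ± 4717 CPM, and miR-96-5p rose 3.96-fold, from 79.9 ± 35.4 to 316 ± 11.3 CPM. In the miR-200 family, miR-200c-3p rose 7.25-fold (120 ± 71.9 to 874 ± 381 CPM), miR-141-3p rose 6.90-fold (86.9 ± 61.6 to 601 ± 237 CPM) and miR-200a-3p rose 6.42-fold (1334 ± 931 to 8567 ± 3053 CPM). miR-200b-3p, miR-429-3p and the passenger strands miR-200a-5p and miR-200b-5p rose by 5.06 to 6.33 times. With single libraries left out, the log2 fold change of miR-183-5p ranged from 2.56 (without ischemia-reperfusion library 1) to 3.64 (without ischemia-reperfusion library 2). That of miR-141-3p ranged from 2.38 (without sham library 3) to 3.39 (without sham library 7).

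In log2 units with standard errors, the changes were 3.29 ± 0.53 for miR-183-5p, 2.73 ± 0.44 for miR-182-5p, 1.99 ± 0.34 for miR-96-5p and 2.86 ± 0.49 for miR-200c-3p. Each of these had an adjusted p of 0.0247 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By the same edgeR test and adjustment, the changes were 2.66 ± 0.52 for miR-200b-3p, 2.59 ± 0.48 for miR-200a-5p, 2.35 ± 0.45 for miR-200b-5p and 2.34 ± 0.46 for miR-429-3p, with an adjusted p of 0.0325. miR-141-3p changed by 2.79 ± 0.57 (adjusted p = 0.0366) and miR-200a-3p by 2.68 ± 0.56 (adjusted p = 0.0416), again with edgeR and Benjamini-Hochberg adjustment. For each of these 10 miRNAs, all 3 ischemia-reperfusion values lay above all 3 sham values. Together they held 0.201%, 0.520% and 0.728% of normalized counts in sham libraries 3, 6 and 7, and 5.14%, 2.24% and 2.75% in ischemia-reperfusion libraries 1, 2 and 3. The sham libraries also differed widely among themselves. miR-200a-3p stood at 362, 1423 and 2217 CPM in sham libraries 3, 6 and 7, and miR-141-3p at 22.8, 92.4 and 146 CPM. In log2 units from the sham mean, the miR-200 members among the 10 averaged −1.31 in sham library 3 and 0.84 in sham library 7. After ischemia-reperfusion they averaged 2.49 to 3.36.

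**Figure D1:**
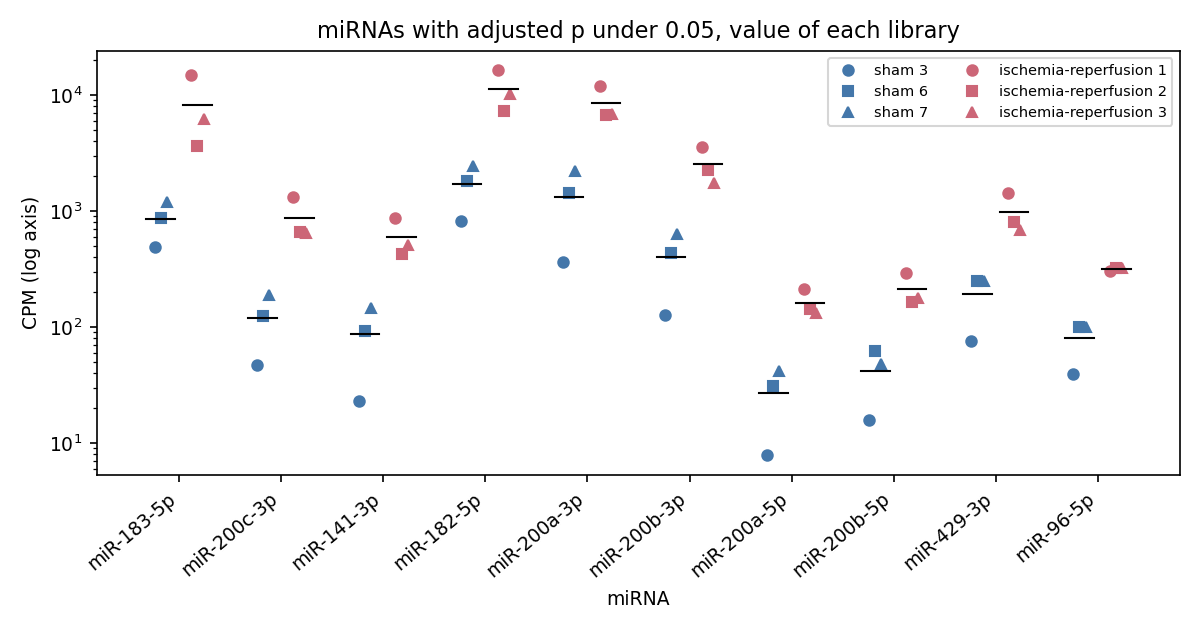
Normalized counts (CPM, log axis) of the 10 miRNAs with an adjusted p under 0.05, 1 point per library, blue for sham and red for ischemia-reperfusion, with a bar at each group's mean of 3 libraries. For miR-183-5p the sham mean and the ischemia-reperfusion mean are 847 and 8256 CPM, and no value of the second group falls within the range of the first.

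The 3 hairpins of the miR-183 cluster lie within 3820 bp of chromosome 6 (GRCm38, 30165918 to 30169737, minus strand), outside other annotated genes. The hairpins of miR-200b, miR-200a and miR-429 lie within 1846 bp of chromosome 4 (156053905 to 156055750, minus strand), in an intron of the protein-coding gene Ttll10, and that of miR-429 also overlaps an exon of the processed transcript Gm13648. The hairpins of miR-200c and miR-141 lie within 477 bp of chromosome 6 (124717914 to 124718390, minus strand), in an intron of the noncoding gene Gm15884, and that of miR-141 also overlaps an exon of the unclassified transcript Gm29008.

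Of 440 miRNAs tested, these 10 were the ones past an adjusted p of 0.05 with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, all 10 higher and 0 lower after ischemia-reperfusion. At the same adjusted threshold DESeq2 called 22 higher and 4 lower, and limma-voom called 10 higher and 0 lower. At an unadjusted p under 0.05 edgeR gave 46 higher and 28 lower. The groups did not overlap for 96 miRNAs (21.8%, against 10% by chance for 3 against 3). The edgeR count was 0 without sham library 6 (44 at an unadjusted p under 0.05) and 0 without ischemia-reperfusion library 3 (57 at an unadjusted p under 0.05), and 4 with RLE size factors or with the 5 most abundant miRNAs left out. It was 1 without ischemia-reperfusion library 1 and 100 without ischemia-reperfusion library 2 (58 higher, 42 lower). Library 2 lay nearest to sham within its group, so leaving it out favours calls. The lowest log2 fold change among the 10, 1.99 with all libraries, was 2.23 without sham library 6, 2.03 without ischemia-reperfusion library 3, 1.96 without ischemia-reperfusion library 1, and 2.03 with RLE size factors or without the 5 most abundant miRNAs.

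**Figure D2:**
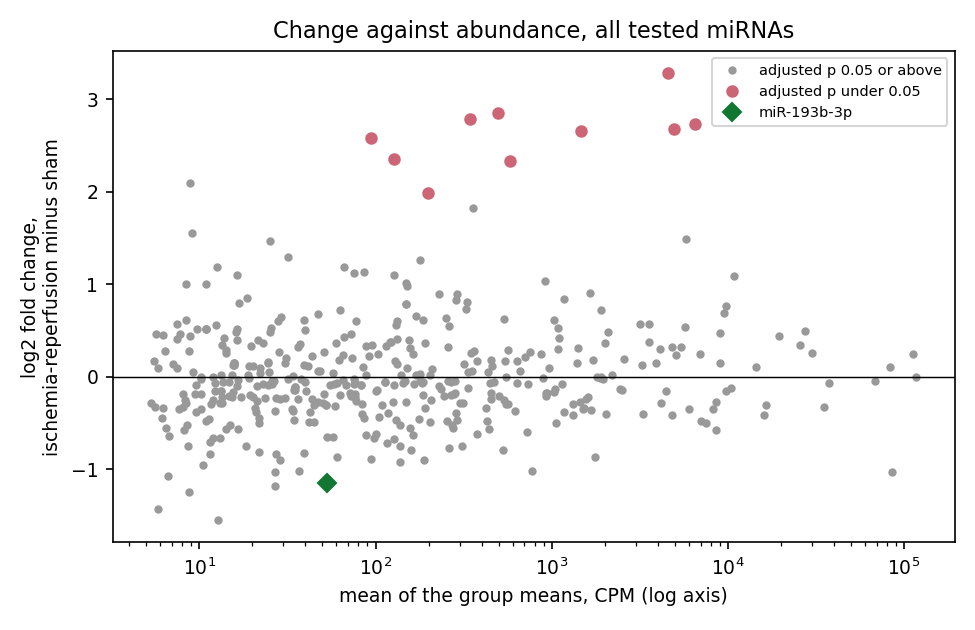
Log2 fold change (ischemia-reperfusion minus sham) against the mean of the group means in CPM (log axis) for the 440 tested miRNAs, 1 point each. The 10 red points, with an adjusted p under 0.05, lie between 1.99 and 3.29, and the green diamond marks miR-193b-3p at −1.16.

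miR-193b-3p, the miRNA that the study's title names as cargo of astrocyte exosomes, averaged 73.7 ± 11.7 CPM in sham brain and 33.0 ± 18.6 CPM after ischemia-reperfusion (SD, n = 3 each), 0.449 of the sham level. Its values were 73.3, 85.6 and 62.1 CPM in sham libraries 3, 6 and 7 and 17.4, 53.6 and 28.0 CPM in ischemia-reperfusion libraries 1, 2 and 3, with no overlap. The log2 fold change of −1.16 ± 0.36 did not pass the threshold over all miRNAs (adjusted p = 0.157, edgeR quasi-likelihood test, Benjamini-Hochberg). A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allow. Adjusted over the list alone, the list of miR-193 and miR-365 with 2 tested members, it passed (adjusted p = 0.0218, edgeR, Benjamini-Hochberg), but not without sham library 3 (0.0561), sham library 6 (0.0979) or ischemia-reperfusion library 3 (0.115). The study's title had already singled out miR-193b-3p, so passing over 2 members is no independent support for it. Its neighbour miR-365-3p measured 20.9 ± 6.22 and 17.8 ± 6.78 CPM, a log2 difference of −0.20 ± 0.34 (adjusted p = 0.772, edgeR, Benjamini-Hochberg). miR-193a-3p, with 48 counts in all 6 libraries together, was too low to test. Without ischemia-reperfusion library 2 the miR-193b-3p log2 fold change was −1.67 and passed over all miRNAs (adjusted p = 0.00696, edgeR, Benjamini-Hochberg). The Mir193b hairpin lies at 13449523 to 13449601 on the plus strand of chromosome 16 (GRCm38), within an intron of the antisense gene Gm15738 on the opposite strand. Mir365-1 lies at 13453840 to 13453926 in the same intronic context.

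Of the miRNAs that respond to inflammation, miR-155-5p and miR-146a-5p, which dampen or tune Toll-like receptor and NF-κB signalling in immune cells and glia, had the higher means after ischemia-reperfusion. miR-155-5p averaged 18.3 ± 1.35 CPM in sham and 45.2 ± 23.3 CPM after ischemia-reperfusion, and miR-146a-5p 3024 ± 381 and 8500 ± 5672 CPM. Over all miRNAs edgeR with Benjamini-Hochberg adjustment called 0 of the 6 tested members of the inflammation-induced list (3 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 these 2. Adjusted over the list alone these 2 rose, with log2 fold changes of 1.30 ± 0.39 (adjusted p = 0.0490) and 1.49 ± 0.51 (adjusted p = 0.0491, edgeR, Benjamini-Hochberg). With single libraries left out, both passed over the list without ischemia-reperfusion library 2 and neither did without any of the other 5 (adjusted p 0.0879 to 0.205, log2 fold changes 0.93 to 1.60, edgeR, Benjamini-Hochberg). The other members included miR-21a-5p, with 7195 ± 988 and 12219 ± 5399 CPM, and miR-146b-5p, with 2873 ± 64.7 and 4264 ± 1610 CPM. In ischemia-reperfusion library 2, miR-146a-5p stood at 2268 CPM and miR-155-5p at 21.2 CPM, near the sham values. They stood at 13359 and 67.6 CPM in library 1 and 9874 and 46.8 CPM in library 3. The list as a whole did not pass (camera adjusted p = 0.135, Benjamini-Hochberg over 21 lists). Of the 6 tested members of the leukocyte and microglia list, edgeR called 0 over all miRNAs (2 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 miR-155-5p. Adjusted over the list alone, miR-155-5p and miR-142a-5p rose (both adjusted p = 0.0402, edgeR, Benjamini-Hochberg). They too passed without ischemia-reperfusion library 2 and not without any of the other 5 libraries (0.0569 to 0.136, log2 fold changes 0.73 to 1.40). miR-142a-5p, a miRNA of blood-forming cells, measured 40.2 ± 5.69 and 91.6 ± 50.6 CPM, with 43.0 CPM in ischemia-reperfusion library 2. The neutrophil miRNA miR-223-3p measured 14.3 ± 7.36 and 6.73 ± 8.86 CPM. Its second mean rests on ischemia-reperfusion library 3 (16.9 CPM), without which the log2 difference moved from −0.96 to −3.02. miR-142a-3p measured 47.2 ± 4.28 and 78.1 ± 36.7 CPM (camera adjusted p of the list 0.429, Benjamini-Hochberg).

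**Figure D3:**
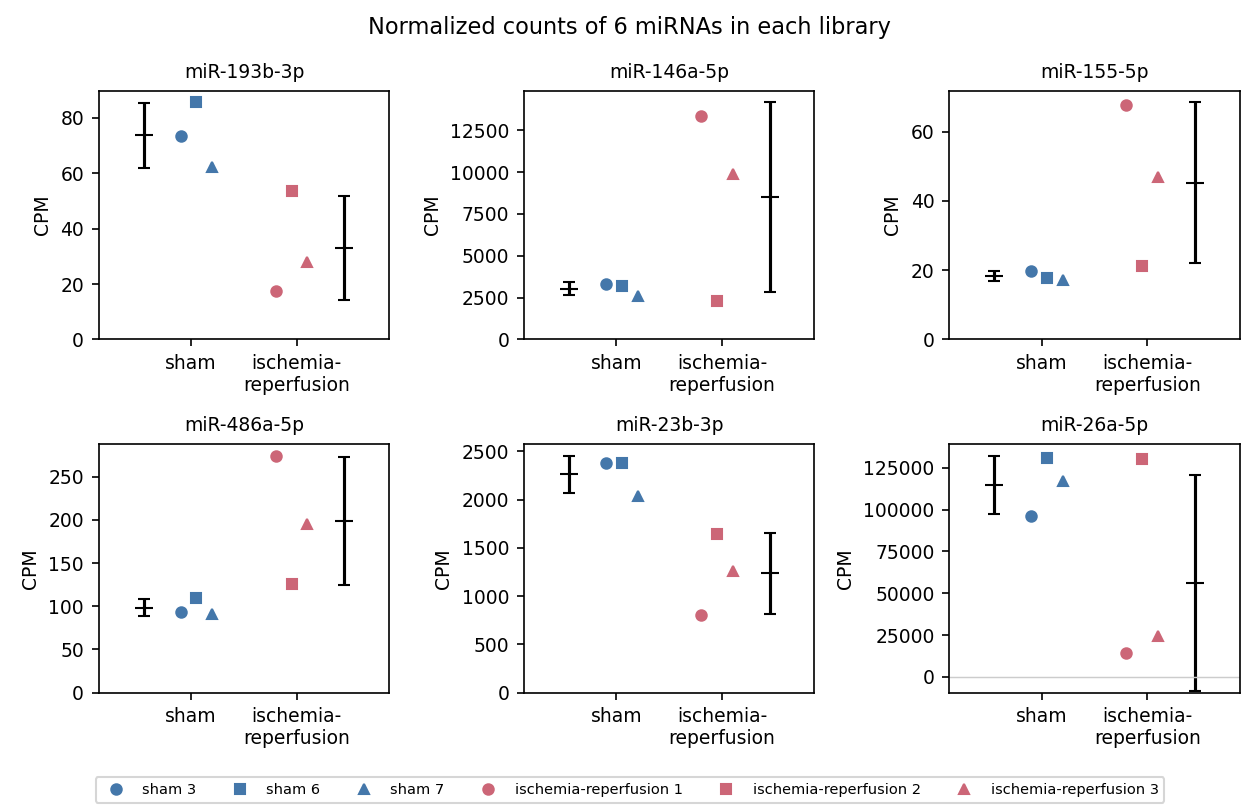
CPM of miR-193b-3p, miR-146a-5p, miR-155-5p, miR-486a-5p, miR-23b-3p and miR-26a-5p in each library (points, linear axis), with the mean and SD of each group of 3 in black beside the points. With edgeR and Benjamini-Hochberg adjustment 0 of the 6 passed over all miRNAs, and DESeq2 called miR-146a-5p, miR-155-5p and miR-486a-5p. Ischemia-reperfusion library 2 (square) lies nearest to the sham values within its group in each panel, as for miR-146a-5p at 2268 CPM.

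Among miRNAs of red blood cells, miR-486a-5p and miR-486b-5p, with nearly the same counts in each library, had higher means after ischemia-reperfusion. miR-451a, with the highest group means of the list, had a lower one. miR-486a-5p averaged 98.2 ± 9.83 CPM in sham and 198 ± 74.3 CPM after ischemia-reperfusion, and miR-486b-5p, whose reads cannot be separated from it with certainty, 101 ± 12.8 and 200 ± 73.4 CPM. In ischemia-reperfusion library 2 miR-486a-5p stood at 126 CPM, and in library 1 at 274 CPM. miR-451a measured 300 ± 29.0 and 266 ± 14.1 CPM. Of the 5 tested members of the erythrocyte list, edgeR called 0 over all miRNAs (2 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 miR-486a-5p and miR-486b-5p. These 2 rose adjusted over the list alone (both adjusted p = 0.0174, edgeR, Benjamini-Hochberg, with a camera adjusted p of the list of 0.275). Their counts, such as 410 and 411 in ischemia-reperfusion library 1, make them largely 1 measurement. The 2 calls are thus not independent, and counting both eases the adjustment over the list. They did not pass over the list without sham library 3 (0.0557) or sham library 7 (0.0819), with log2 fold changes of 0.92 to 1.02. Of the 6 tested vessel wall miRNAs, edgeR, DESeq2 and limma-voom called 0 (1 at an unadjusted p under 0.05 by edgeR), with miR-143-3p of smooth muscle at 39285 ± 7586 and 31321 ± 8785 CPM (camera adjusted p = 0.992). In the liver list, edgeR called 0 of 3 tested members over all miRNAs (2 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 miR-122-5p (camera adjusted p of the list 0.135). Adjusted over the list alone 2 rose with edgeR. These were miR-122-5p, the abundant hepatocyte miRNA, at 13.1 ± 4.39 and 37.2 ± 23.0 CPM (adjusted p = 0.0297), and miR-192-5p, at 814 ± 172 and 1248 ± 272 CPM (adjusted p = 0.0402, edgeR, Benjamini-Hochberg). Without ischemia-reperfusion library 1, at 63.6 CPM, the log2 fold change of miR-122-5p moved from 1.47 to 0.86 and did not pass over the list (adjusted p = 0.0897, edgeR, Benjamini-Hochberg). Nor did it without sham library 3 (0.0610) or 6 (0.112), and miR-192-5p did not pass without any 1 of these 3 libraries or ischemia-reperfusion library 3 (0.0621 to 0.135).

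The lists enriched in neurons, astrocytes and oligodendrocytes, and the other lists of this paragraph, had 0 members past the threshold, over all miRNAs or adjusted over the list alone, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, and DESeq2 and limma-voom called 0 over all miRNAs (0 to 2 per list at an unadjusted p under 0.05 by edgeR). Of the 16 tested neuron-enriched miRNAs, 12 had negative log2 differences (camera adjusted p = 0.213). Among them, miR-128-3p measured 8160 ± 420 CPM in sham and 5860 ± 1401 CPM after ischemia-reperfusion, and miR-9-5p 69858 ± 11037 and 67551 ± 5645 CPM. Of 11 astrocyte-enriched miRNAs, 8 were negative, with miR-23b-3p at 2265 ± 192 and 1237 ± 418 CPM, 1645 CPM in ischemia-reperfusion library 2 and no overlap between the groups (camera adjusted p = 0.566). Among 4 oligodendrocyte-enriched miRNAs, miR-219a-2-3p measured 600 ± 48.1 and 1226 ± 711 CPM, with 578 CPM in ischemia-reperfusion library 2 (camera adjusted p = 0.391). miR-219a-5p of the same list measured 115 ± 24.4 and 110 ± 30.8 CPM. In the list of choroid plexus and ependyma, 4 of the 6 tested members had positive and 2 negative log2 differences (camera adjusted p = 0.531). Of the negative ones, miR-204-5p measured 473 ± 42.5 CPM in sham and 373 ± 62.2 CPM after ischemia-reperfusion. Of the positive ones, the miRNA of ciliated cells miR-34c-5p measured 1439 ± 192 and 2375 ± 680 CPM. miR-34c-5p is also a target of p53, and all 5 tested members of the p53-induced miR-34 list had log2 differences above 0, without passing (camera adjusted p = 0.193). Of 8 activity-regulated miRNAs, miR-184-3p measured 61.2 ± 4.99 and 93.2 ± 6.96 CPM without overlap, a log2 difference of 0.61 ± 0.20 (adjusted p = 0.157, edgeR, Benjamini-Hochberg; camera adjusted p of the list 0.992). miR-210-3p, the best known hypoxia-induced miRNA and the 1 tested member of its list, measured 45.9 ± 4.05 and 47.9 ± 9.26 CPM, a log2 difference of 0.060 ± 0.22.

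As lists, epithelial and pituitary miRNAs were higher and miRNAs of the imprinted Dlk1-Dio3 cluster, many of them expressed in neurons, were lower after ischemia-reperfusion by camera with a preset correlation, though not with an estimated one. In the epithelial and pituitary list, 10 of 14 tested members rose over all miRNAs and 12 rose adjusted over the list alone, with a median log2 fold change of 2.47 (camera adjusted p = 3.02e-13, Benjamini-Hochberg over 21 lists). The list did not pass with a correlation estimated from the data (camera adjusted p = 0.667) or with fry (0.180). Beyond the 10, miR-141-5p measured 3.32 ± 2.88 and 14.4 ± 3.74 CPM, and miR-375-3p, abundant in pituitary and pancreatic islets, 36.2 ± 8.15 and 58.4 ± 18.5 CPM; these were singled out after their values were seen. With each library left out in turn, 11 of the 12 passed over the list every time by edgeR with Benjamini-Hochberg adjustment. miR-375-3p did not pass without sham library 3 (0.0973), sham library 6 (0.133) or ischemia-reperfusion library 1 (0.138). miR-7b-5p stood at 27501 ± 1807 and 32874 ± 5009 CPM and miR-7a-5p at 117935 ± 12148 and 117407 ± 35980 CPM. Of the 70 tested Dlk1-Dio3 miRNAs, edgeR with Benjamini-Hochberg adjustment called 0 over all miRNAs or adjusted over the list alone (12 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 miR-154-5p and miR-337-5p, both lower. Of these 70, 53 had negative and 17 positive log2 differences, with a median of −0.25 (camera adjusted p = 0.000204). This list too did not pass with an estimated correlation (camera adjusted p = 0.696) or with fry (0.306). The lowest p in that cluster belonged to miR-337-5p (37.7 ± 7.70 and 16.4 ± 5.59 CPM, with 22.4 CPM in ischemia-reperfusion library 2) and miR-154-5p (246 ± 30.3 and 131 ± 38.4 CPM), whereas its abundant member miR-379-5p measured 22570 ± 2322 and 28570 ± 10768 CPM.

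In the muscle list and the other lists of this paragraph, edgeR with Benjamini-Hochberg adjustment, DESeq2 and limma-voom called 0 members over all miRNAs (0 to 2 per list at an unadjusted p under 0.05 by edgeR). Of the 5 tested muscle miRNAs, miR-206-3p, a miRNA of skeletal muscle, measured 1432 CPM in ischemia-reperfusion library 1 and 92.9 to 226 CPM in the other 5 libraries (camera adjusted p = 0.530, Benjamini-Hochberg). Without library 1 its log2 difference moved from 1.82 to −0.33. miR-1a-3p measured 13943 ± 2659 and 14982 ± 4585 CPM, and miR-133a-3p 59.5 ± 19.7 and 56.5 ± 4.73 CPM. Of the 9 tested let-7 and miR-98 miRNAs, let-7i-5p measured 22853 ± 1236 and 32266 ± 8269 CPM without overlap (camera adjusted p = 0.992, with a median log2 difference of −0.14 and a camera direction of up). The miR-15 and miR-16 family (5 tested) and miR-181 (8 tested) also had a camera adjusted p of 0.992. Their medians, −0.033 and 0.10, were opposite in sign to the direction of the test. The 10 tested miR-30 miRNAs, with miR-30a-5p at 103627 ± 20141 and 122392 ± 21802 CPM, did not pass as a list (camera adjusted p = 0.553). The same held for the 11 tested miRNAs of miR-17 to 92 and its paralogs and the 20 of the Sfmbt2 cluster (both camera adjusted p = 0.391). Among 5 entries that overlap fragments of other RNAs, miR-6239 fell adjusted over the list alone, from 37.4 ± 8.51 to 20.0 ± 3.75 CPM (adjusted p = 0.0356, edgeR, Benjamini-Hochberg), and the list did not pass (camera adjusted p = 0.391). With single libraries left out, miR-6239 passed over the list without ischemia-reperfusion library 2 and not without any of the other 5 (0.0738 to 0.268, log2 fold changes −0.96 to −0.70). The 2 tested Hox-locus miRNAs, miRNAs of the caudal body axis, had positive log2 differences, with a median of 0.53.

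None of the 10 most abundant miRNAs passed with edgeR and Benjamini-Hochberg adjustment, DESeq2 or limma-voom. miR-26a-5p stood at 96420, 131052 and 117048 CPM in sham libraries 3, 6 and 7 and at 13990, 130209 and 24260 CPM in ischemia-reperfusion libraries 1, 2 and 3. The log2 difference was −1.03 ± 0.69 (adjusted p = 0.437, edgeR quasi-likelihood test, Benjamini-Hochberg), and −2.59 without ischemia-reperfusion library 2 (adjusted p = 0.00275). miR-101a-3p measured 79971 ± 6194 and 86283 ± 23239 CPM, and miR-101b-3p 38321 ± 1671 and 36580 ± 6739 CPM. For miR-7a-5p, with the highest mean of the 2 group means but not the highest value in every library, the sign of a log2 difference of −0.0065 ± 0.28 changed with the scaling (0.032 with RLE size factors).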

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

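The sum of repeated rows, all rows kept apart and a fit without the miR-183 and miR-200 groups were alternatives chosen after the data were seen. The count of 10 miRNAs stayed between 9 and 10 with upper-quartile or total-count scaling, both other filters, limma-voom, robust estimation and both treatments of repeated rows. It was 4 with RLE size factors, 4 with the 5 most abundant miRNAs left out, and 26 with DESeq2 (22 higher, 4 lower, all 10 included). It was 33 at an unadjusted p under 0.05 with a 2-fold change, and 0 without the miR-183 and miR-200 groups, which by construction removes the 10; the other causes were not tested. With single libraries left out it ranged from 0 (without sham library 6 or ischemia-reperfusion library 3) to 100 (without ischemia-reperfusion library 2). miR-193b-3p kept its sign in all settings, from −1.67 to −0.85 with single libraries left out and from −1.28 to −1.09 otherwise, and passed the threshold only without ischemia-reperfusion library 2. The 2 lists called became 1 without the miR-183 and miR-200 groups, 0 with an estimated correlation and 0 with fry. The adjusted p of the epithelial and pituitary list was then 0.282, 0.667 and 0.180, and that of Dlk1-Dio3 was 0.696 with an estimated correlation and 0.306 with fry. With all libraries kept, signs turned for miR-7a-5p, miR-9-5p and miR-101b-3p. miR-7a-5p (−0.0065) was 0.032 with RLE, 0.028 with upper-quartile factors, 0.029 without a filter, 0.027 with the 10 CPM filter, 0.032 with DESeq2, 0.055 with summed rows, 0.0052 with all rows and 0.056 without the miR-183 and miR-200 groups. miR-9-5p (−0.048) was 0.015 with summed rows and 0.023 without those groups, and miR-101b-3p (−0.067) was 0.0054 without them; these causes were not tested. With single libraries left out, the range included both signs for miR-101a-3p (−0.11 to 0.26), miR-101b-3p (−0.20 to 0.051), miR-133a-3p (−0.28 to 0.25), miR-1a-3p (−0.076 to 0.33), miR-206-3p (1.82 with all, −0.33 to 2.34), miR-210-3p (−0.11 to 0.19), miR-365-3p (−0.52 to 0.078), miR-7a-5p (−0.12 to 0.24) and miR-9-5p (−0.099 to 0.088). Of the other values of named miRNAs, 215 kept their side of the threshold with a library left out, 22 passed it newly and 30 no longer passed; with other settings the numbers were 515, 8 and 14. No paired analysis was possible because the groups share only 1 replicate number. Pseudocounts for normalized values were not run, since the values are counts.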

Other observations

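The tests of scaling, tissue share, hairpin arms and muscle below were chosen after the results were seen; the counts of other splits were planned.

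Away from the miR-183 and miR-200 groups, the ischemia-reperfusion libraries differed from one another more than the sham libraries did. The 430 tested miRNAs other than the 10 past the threshold were compared, which include miR-141-5p of the miR-200 family. Of these 430, 90 in ischemia-reperfusion library 1 (37 higher, 53 lower) lay more than 2-fold from the sham mean. So did 34 in library 3 (16 higher, 18 lower) and 7 in library 2. Against the mean of the other sham libraries, 4, 6 and 9 did so in sham libraries 3, 6 and 7. Library 2 nevertheless held 2.24% of its counts in the 10 miRNAs that rose, above the 0.201% to 0.728% of sham. Library 2 lay nearest to sham within its group, so leaving it out favours calls, and it leaves 2 ischemia-reperfusion libraries. The calls without it are therefore no separate support for a change. Without library 2, edgeR with Benjamini-Hochberg adjustment called 100 miRNAs, of which 89 lay outside the 2 groups. Among these, miR-26a-5p (log2 −2.59, adjusted p = 0.00275), miR-23b-3p (−1.13, 0.0116), miR-128-3p (−0.68, 0.0283) and miR-337-5p (−1.46, 0.0104) were lower, and miR-146a-5p (1.94, 0.00275), miR-155-5p (1.63, 0.00433), miR-21a-5p (1.02, 0.0151) and miR-219a-2-3p (1.36, 0.00802) were higher. With all 6 libraries edgeR with Benjamini-Hochberg adjustment called 0 of these 8, and DESeq2 called miR-146a-5p, miR-155-5p and miR-337-5p. Over all settings run the adjusted p of miR-146a-5p ranged from 0.00275 to 0.515 and that of miR-26a-5p from 0.00275 to 0.747.

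The miR-183 and miR-200 groups, from 3 loci on 2 chromosomes, rose together. The median log2 change of the epithelial and pituitary list, fixed before the data were examined, exceeded that of the other tested miRNAs by 2.55, the median over the 9 pairs of a sham and an ischemia-reperfusion library (1.64 to 4.41, total-count scaling). A factor common to a library cancels in this difference, so scaling alone would not give it. The list was picked for this comparison with its rise known, so the size of the difference restates that rise. A candidate explanation is a differing share of tissue or cells rich in these miRNAs, such as epithelium or pituitary. Of the 14 tested members of that list, 13 had counts in every sham library. Such a share should also vary within a group. The mean deviations of the 2 groups from the group means correlated at 0.951 over 6 libraries, above 96.8% of 10000 expression-matched pairs of single miRNAs. Means carry less noise than single miRNAs, so the 2 sides are unlike and the percentile is too high. The median over pairs of single members was 0.869, below the 95th percentile of the draws (0.927). Exact permutation of the libraries within groups (36 arrangements) gave p = 0.0556. The test does not decide, since each group moves as 1 unit over 6 libraries. Shared regulation by ischemia-reperfusion would also move both and was not tested. The pituitary miRNAs miR-375-3p, miR-7b-5p and miR-7a-5p differed by 0.68, 0.26 and −0.0065. In sham, miR-7b-5p averaged 27501 CPM and miR-7a-5p 117935 CPM, a baseline that would hide a small share. This limit does not hold alike for miR-375-3p, which averaged 36.2 CPM in sham and 58.4 CPM after ischemia-reperfusion. As 1 member of the list it does not settle the question. Among the 10 splits of the 6 libraries, 1, the real one, gave 10 calls and the highest of the others 0; 10 splits are too few for a share under 0.05.

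For the list tests, 7 of the 10 splits, the real one included, gave at least as many lists past the threshold as the real 2. The highest of the others was 3. The number of lists called thus did not set the real split apart, and 10 splits could not have given a share under 0.05 in any case. The camera calls rest on the preset correlation, since 0 lists passed with an estimated one.

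The deviations of ischemia-reperfusion libraries 1 and 3 may come from transcription of hairpins or from cell content, which should move both arms of a hairpin. Across 96 hairpins outside these groups, log2 changes from library pairs that share no library correlated at 0.321 for the same arm. They correlated at 0.0551 between arms (95% bootstrap interval −0.0536 to 0.164). For the 26 hairpins with both arms at 100 CPM or more, the correlations were 0.303 and 0.00063. The 18 comparisons took in all 3 ischemia-reperfusion libraries, library 2 included, which deviated little. They thus do not test libraries 1 and 3 alone. For 44 hairpins the arms changed in opposite directions, but the share that unrelated arms would give was not computed. Over the 96 hairpins, the same-arm correlation exceeded that between arms by 0.266 (95% interval 0.127 to 0.399). This argues against arms that moved equally in these comparisons. The interval between arms still reached 0.160, the bound set for arms of unequal lifetime, so the explanation cannot be told apart from changes specific to a strand. RNA quality, ligation and the severity of ischemia in each animal were not measured in these tables and stay open.

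miR-206-3p was higher in ischemia-reperfusion library 1 than in the mean of the other 5 libraries by 3.36 in log2, with an SD of 0.49 among those. Muscle tissue in that sample should also bring miR-1a-3p, miR-133a-3p and miR-133b-3p. These differed by 0.49 (SD of the others 0.33), 0.098 (SD 0.34) and 0.43 (SD 0.35), with 0.43 as their median. The bound set for muscle was a rise of each by more than 2-fold, and none reached it. The differences of 2 of them lay above the SD of the other libraries by too little to count for muscle, and that of miR-133a-3p lay within it. The baseline of miR-1a-3p would hide a small share. That of miR-133a-3p was far lower, at 40.9 to 80.1 CPM in the other 5 libraries, and it stood at 60.2 CPM in library 1. miR-133a-3p thus gave no sign of muscle, but values of 1 library cannot settle the source.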
